A study of Mus musculus with 4 samples.

How the data were processed

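H3K27ac, an acetylation of histone H3 found at active promoters and enhancers, was profiled by fanChIP (fractionation-assisted native chromatin immunoprecipitation) and sequencing in mouse bone marrow cells of the C57BL/6 strain. The labels name 4 samples: a control ChIP library, a BN1 ChIP library (BN1 is the submitters' name for BRD9-NUTM1) and an input library for each. The 2 ChIP libraries were analysed, each through 1 peak list, and the 2 input libraries and the other leukaemias that the series describes were not analysed here. The extract protocol in the labels names cKit-positive BN1 cells for every sample, the controls included.

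The deposited files are narrowPeak lists without a header. Bowtie2 2.5.4, Picard 3.2.0, deepTools 3.5.1 and MACS3 3.0.1 and the build mm10 (GRCm38) are named in the submitters' processing notes, with no role or order given. Whether the input was subtracted, whether libraries were pooled before calling and which threshold was set are not given in the sources used here. Each deposited peak carries the authors' fold enrichment at its summit as a linear ratio, the −log10 of its p-value, the −log10 of its q-value, and a score. That score lay within 1 unit of 10 times the −log10 q in 100% of the deposited peaks of both lists and was not used further. The lowest deposited −log10 q was 1.32 in the control list and 1.30 in the BN1 list. The fold enrichment is the peak's own value within its list and was used only to describe or rank peaks of that list. Read depth is unknown, because the lists hold no read counts, and depth limits which weak regions could be called in either library.

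Groups were taken from the sample titles. The prefix of the peak names inside the lists reads the other way from the titles: peaks of the list assigned to the control sample are named BRNU, and peaks of the list assigned to the BN1 sample are named BM. These abbreviations are not explained in the labels. Groups follow the titles throughout, as "the list labelled control" and "the list labelled BN1", and every direction below holds for the labels only.

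Peaks did not overlap within a list, so each peak was kept as 1 region. Peaks were called shared where they overlapped at least 1 bp of a peak of the other list (bedtools 2.31.1). Genes came from a RefSeq table of GRCm38.p6, the same assembly as mm10, with 21887 protein-coding genes on the chromosomes. The table gives both ends of each gene but no strand, so a promoter could not be told from a 3' end. The planned promoter measure was replaced by a region within 1000 bp of either gene end. No genome sequence was used here, so the planned motif comparison was not run. The acetylated length of a gene is the number of bp covered by peaks from 10 kb before its lower end to 10 kb after its upper end, and it was also expressed as bp per Mb of the list's total covered length. Neighbouring genes can share a region.

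There was 1 library per group and therefore no replicate error. No p-value was computed, and differences describe these 2 libraries. For 22 gene lists fixed before the data were examined, the median difference in acetylated length per Mb (BN1 minus control) was set against 10000 random lists of the same size, matched on mean acetylated length in 20 bins, and given as a percentile. The percentile describes these libraries, since genes are not replicates and neighbours share regions. Of 375 listed genes, 371 were found in the table; Mx1, Mx2, Tpsab1 and Znf532 were not. Values of some listed genes are not reported here. Exact (Clopper-Pearson) 95% binomial intervals cover counting error only. On simulated differences over the same 21887 genes, 12 of 200 unshifted lists of 20 genes fell outside the central 95%, and 100 of 100 lists shifted by 50 bp per Mb lay above it. The simulated lists held only genes with a region in either list, drawn without regard to position, unlike several of the 22. The shift also exceeds the size of some list medians below, so the simulation does not calibrate those lists. Broad domains are peaks stitched within 5 kb with at least 10 kb covered.

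The rule for named genes was set before the data were examined. It took the 10 genes per direction with the largest difference in acetylated length in bp, leaving out predicted genes and overlapping windows, up to 6 members of each list whose end regions differed, the 5 longest domains per list, and Hoxa9, Hoxa10, Meis1, Kit, Cd34, Gata1, Spi1, Cebpa, Myc, Brd9 and Nutm1. Other listed genes named in the text were chosen after their values were seen. Alternatives covered stricter −log10 q minimums (5 and 10), lists of equal length, numbered chromosomes and X only, other overlap rules, other gene end windows (500 and 2500 bp), other flanks (0 and 50 kb), other stitching distances (2 and 12 kb), the length scale and, chosen after seeing the data, the top 10000 peaks of each list. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.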

Results

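The series compared H3K27ac in mouse bone marrow cells carrying BRD9-NUTM1 with that in control marrow cells. BRD9-NUTM1 is a leukaemia fusion of BRD9, a bromodomain subunit of a BAF chromatin remodelling complex, with NUTM1, a testis protein that binds the acetyltransferase p300. The labels describe the sorted cells as CD45.2-positive and positive for cKit, the stem cell factor receptor of blood progenitors. There was 1 ChIP library per group, so no difference below has a replicate check. The list labelled control held 28343 peaks covering 31.0 Mb, and the list labelled BN1 held 19148 peaks covering 19.1 Mb. Median peak width was 755 bp (quartiles 386 and 1452) in the former and 739 bp (quartiles 396 and 1331) in the latter. Sequencing depth is unknown. Peak names inside the lists read the other way from the sample labels, so every direction below is tied to the label and not to an independently checked cell identity.

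The first comparison asked how far the acetylated regions of the 2 libraries coincided. Of the peaks in the list labelled control, 41.2% (95% exact interval 40.6 to 41.8; 11677 peaks) overlapped a peak of the other list. Of those in the list labelled BN1, 62.6% (61.9 to 63.3; 11984 peaks) did so. Both lists covered 12.3 Mb in common, or 32.4% of the 37.9 Mb covered by either. With the longer list limited to as many of its peaks, by −log10 q, as the shorter held, 54.0% of the peaks labelled control and 57.0% of those labelled BN1 were shared. Shared peaks were the stronger ones within each list, with a median fold enrichment of 10.8 against 5.12 for unshared peaks in the list labelled control and 9.48 against 4.81 in the list labelled BN1.

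Shared peaks lay mostly at gene ends and unshared ones mostly away from them. Within 1000 bp of an end of a protein-coding gene lay 65.4% (64.5 to 66.3) of shared and 12.8% (12.3 to 13.3) of unshared peaks in the list labelled control, and 62.8% (62.0 to 63.7) of shared and 14.5% (13.7 to 15.3) of unshared peaks in the list labelled BN1. Unshared peaks lay inside genes in 54.7% of cases in the list labelled control and in 46.0% in the list labelled BN1, and between genes in 32.4% and 39.5%. Of 21887 protein-coding genes, 8395 had an end region in both lists, 1450 in the list labelled control only, 706 in the list labelled BN1 only and 11336 in neither. In the list labelled control 88.9% of the genes with an end region had it at 1 end only, and in the list labelled BN1 91.8%. With lists of equal length the excess on the control side was nearly gone, with 1115 genes in the list labelled control only and 1074 in the list labelled BN1 only, and with the top 10000 peaks of each list it turned, with 1006 and 1651.

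**Figure D1:**
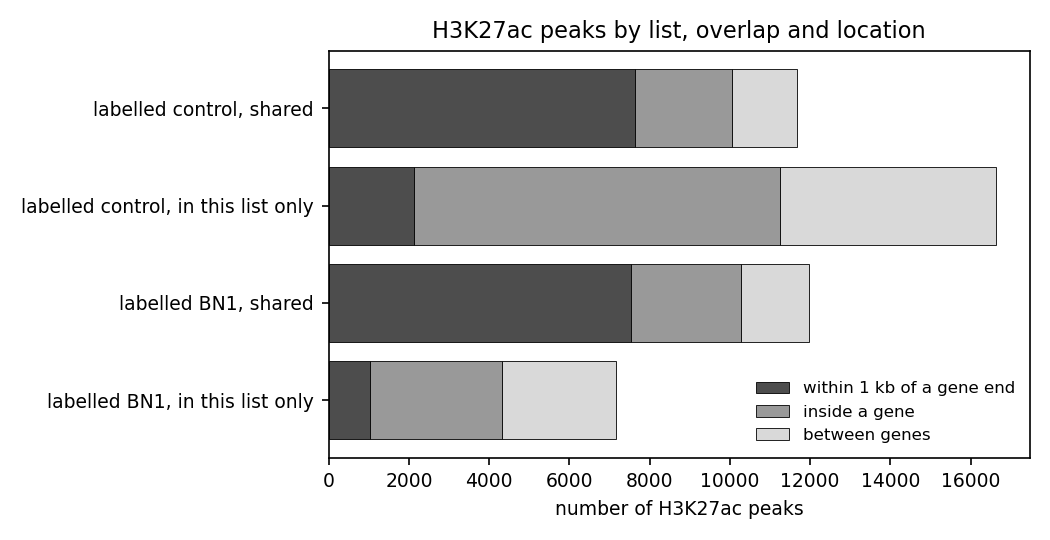
Number of H3K27ac peaks (x axis) in each list, split by overlap with the other list (rows) and by location relative to protein-coding genes (shades). Gene ends made up 65.4% and 62.8% of shared peaks and 12.8% and 14.5% of unshared ones.

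Among 22 gene lists fixed before the data were examined, 8 lay outside the central 95% of matched random lists. Random lists were drawn without regard to position, whereas the Hox genes of a cluster share the same few peaks, so the members of a Hox list are not separate draws. Below it, with relatively more acetylated length in the list labelled control, lay the Hoxa, Hoxb, monocyte and macrophage, and megakaryocyte and platelet lists. Above it, with relatively more in the list labelled BN1, lay the neutrophil and granule, erythroid, B lymphoid and dendritic cell lists. The 2 covered lengths differ 1.62-fold, and over the 13606 genes with a region in either list the median difference, BN1 minus control, was -457 bp but 10.2 bp per Mb of covered length. Group medians are therefore given per Mb, while lengths of single genes and counts of longer members are in bp. Some members counted as longer in the list labelled control turned per Mb. Examples are Slc4a1 (-976 bp but 3.46 bp per Mb), Rag2 (-143 bp but 4.66) and Ly86 (-237 bp but 33.9).

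**Figure D2:**
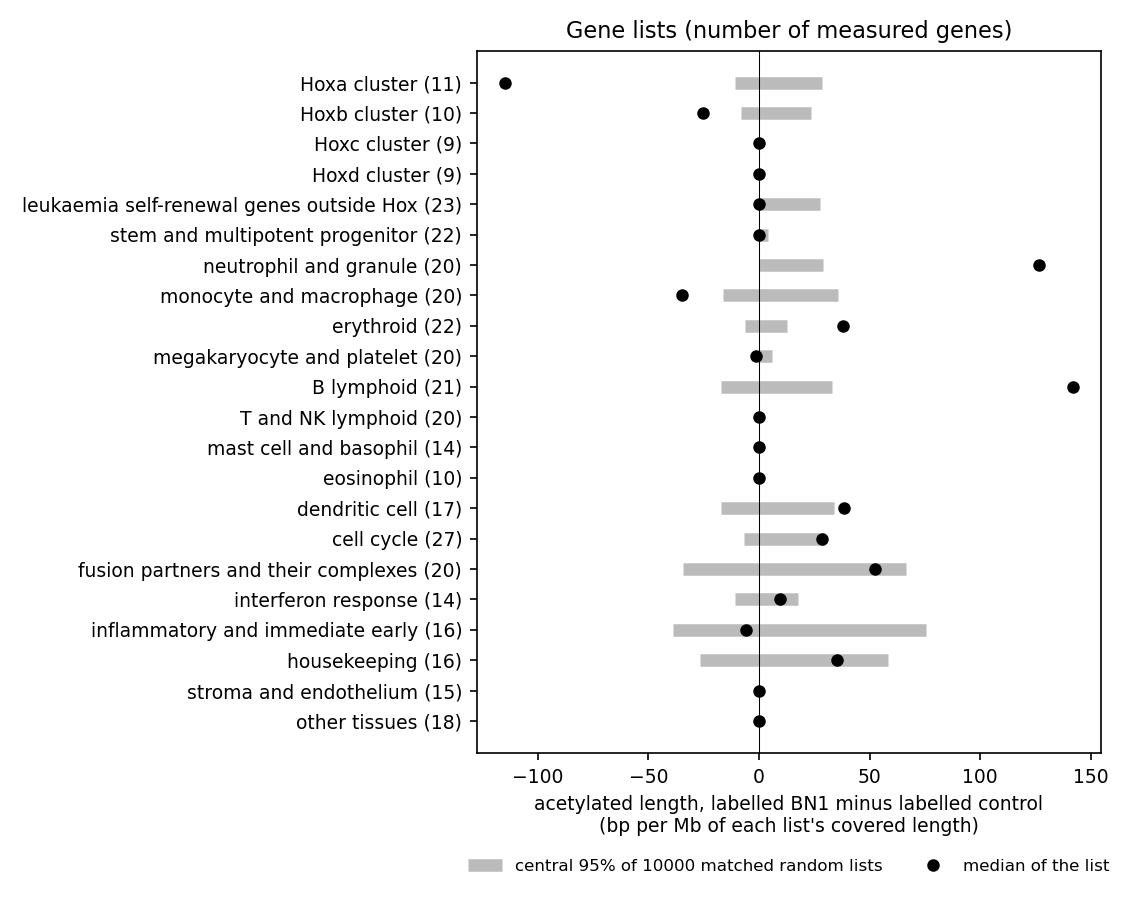
Median difference in acetylated length (x axis, BN1 minus control, bp per Mb of each list's covered length) for the 22 gene lists (rows, with the number of measured genes); points are list medians and grey bars the central 95% of 10000 matched random lists. The Hoxa list stands at -114.7, and the B lymphoid and neutrophil lists at 141.8 and 126.8.

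The Hox genes, which encode homeodomain factors of body patterning and of blood stem and progenitor cells, were acetylated mainly in the list labelled control. Over the Hoxa cluster on chromosome 6 that list had 6 peaks reaching into 10244 bp, with a fold enrichment of up to 18.1. The list labelled BN1 had a single peak of 300 bp with a fold enrichment of 3.14. All of the 9 Hoxa genes with any region had more acetylated length in the list labelled control, and the remaining 2, Hoxa11 and Hoxa13, had none in either list. The list median lay below all 10000 random lists. Hoxa9 had 4046 bp within 10 kb in the list labelled control and 300 bp in the other, and Hoxa10 had 1035 and 300 bp. Neither of these genes had an end region in either list, so these lengths need not belong to them. Hoxa3, Hoxa7, Hoxa2 and Hoxa4 were among the genes with an end region in the list labelled control only. Neighbouring Hox genes share peaks, and without the 10 kb flanks the Hoxa median was 0 (percentile 50).

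The Hoxb cluster (chromosome 11, 96194316 to 96368254) showed the same direction, with 9050 bp in 5 peaks against 1103 bp in 1 peak (list median -25.4 bp per Mb at percentile 0.21). The list median was 0 (percentile 44.4) without flanks, and -76.4 at a −log10 q of at least 10, -96.0 with the top 10000 peaks of each list and -189.0 with 50 kb flanks, each at percentile 0. Hoxb6, Hoxb7 and Hoxb8 shared 5799 bp within 10 kb in the list labelled control and had none in the other, while Hoxb4 had an end region in both. The Hoxc cluster (chromosome 15, 102921131 to 103036856) held 1770 bp in 3 peaks in the list labelled control and no peak in the other. The Hoxd cluster had no peak in either. Meis1, a Hox cofactor, had 2737 bp in the list labelled control and no called region in the list labelled BN1.

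**Figure D3:**
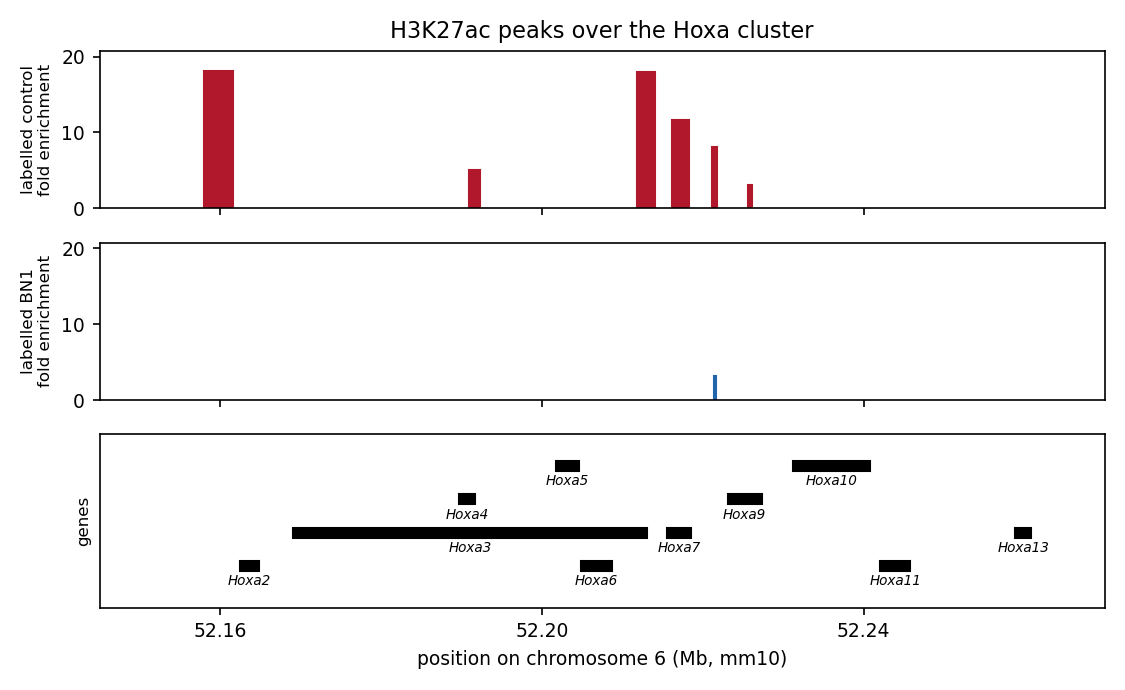
H3K27ac peaks over the Hoxa cluster on chromosome 6 (x axis, Mb, mm10) in the list labelled control (top) and the list labelled BN1 (middle), with the extents of selected genes (bottom, no strand); box height is the authors' fold enrichment, which compares peaks within a list only. The top list has 6 peaks and the middle list 1.

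Monocyte and macrophage genes also had relatively more acetylated length in the list labelled control (median -34.6 bp per Mb, percentile 0.13). The median was -18.6 bp per Mb at a −log10 q of at least 10 and -6.35 (percentile 0.38) with the top 10000 peaks of each list, where 10 genes were longer in the list labelled control and 4 in the list labelled BN1. Of 20 measured genes, 16 were longer in bp in the list labelled control, 3 (Spi1, Irf8 and Csf2ra) were longer in the list labelled BN1, and Ccr2 had no region. By the same count in bp, 12 of 16 housekeeping genes were longer in the list labelled control and 4 in the list labelled BN1. End regions in the list labelled control only were found at 6 genes, among them Cd14, a lipopolysaccharide co-receptor (9481 against 1676 bp), Ctss, the protease cathepsin S (8388 against 813 bp), Cx3cr1, the fractalkine receptor (2315 against 0 bp), Fcgr1 and Adgre1. End regions in both lists were found at 10 genes, and Ly86 had one in the list labelled BN1 only. Among the 10 was Csf1r, the receptor for macrophage colony-stimulating factor, with 6420 against 591 bp. Spi1, which encodes the myeloid factor PU.1, had 9890 bp in the list labelled control and 11921 bp in the list labelled BN1.

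Neutrophil and granule genes showed the opposite direction, with a median of 126.8 bp per Mb, above that of all 10000 random lists. The median was 61.5 bp per Mb at a −log10 q of at least 10 and 7.30 (percentile 98.3) with the top 10000 peaks of each list. Of 20 measured genes, 13 had more acetylated length in the list labelled BN1, 2 (Mmp9 and Cebpa) had more in the list labelled control, and 5 had no region in either. End regions in the list labelled BN1 only were found at 11 genes. Ngp, a granule protein, had 8067 bp against none, S100a9, a subunit of calprotectin, had 6795 bp against none, and Cxcr2, a neutrophil chemokine receptor, had 4835 bp against none. Ltf (lactoferrin) had 3582 bp and Gfi1, a transcription factor required for granulocyte development, had 3480 bp, each with no called region in the list labelled control. The 5 genes without a region were Mpo, Elane, Prtn3 and Ms4a3, which are expressed at the promyelocyte stage, and Ly6g. Cebpa had an end region in both lists, with 1613 bp in the list labelled control and 1331 bp in the list labelled BN1, and its difference changed sign when scaled per Mb (17.6).

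**Figure D4:**
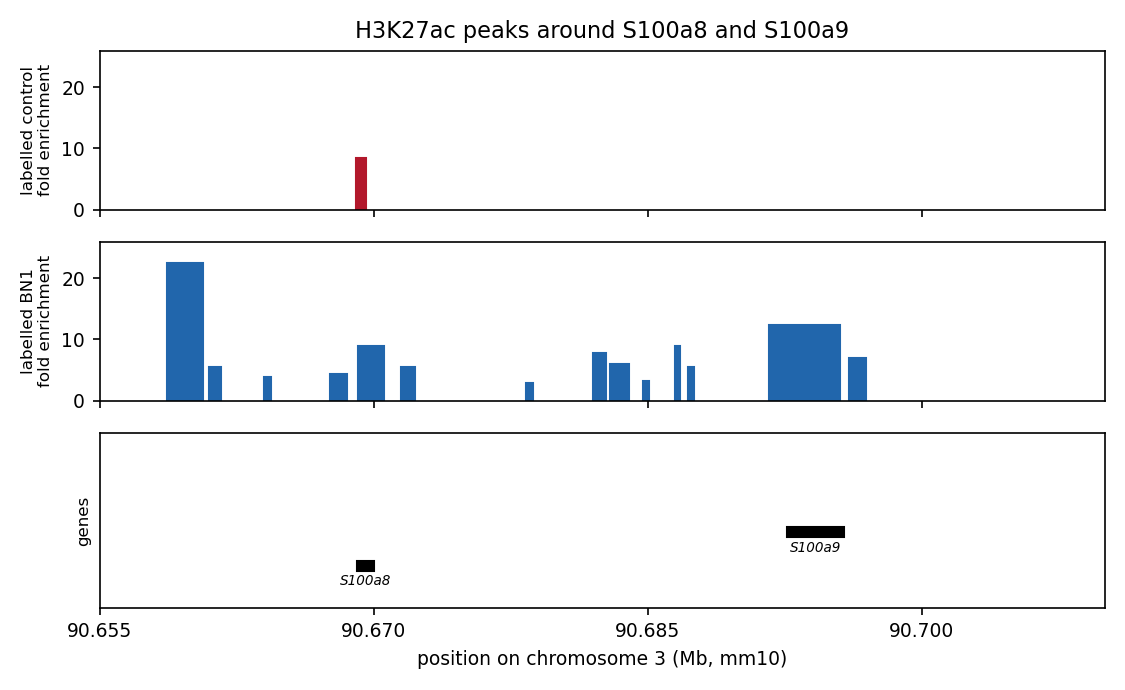
H3K27ac peaks around S100a8 and S100a9 on chromosome 3 (x axis, Mb, mm10) in the list labelled control (top) and the list labelled BN1 (middle), with gene extents (bottom, no strand); box height is the authors' fold enrichment, which compares peaks within a list only. Within 10 kb of S100a9 the list labelled BN1 has 6795 bp and the list labelled control none.

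Erythroid genes had relatively more acetylated length in the list labelled BN1 (median 37.9 bp per Mb, above all 10000 random lists). Of 22 genes, 14 were longer there, 3 (Slc4a1, Ank1 and Epor) were longer in the list labelled control and 5 had no region, among them Gata1, the erythroid master regulator. Nfe2, an erythroid and megakaryocytic factor, had 7832 against 2188 bp. Aqp1, a water channel of red cells, had 2273 bp and Car2, a carbonic anhydrase, had 1642 bp, both with none in the list labelled control. The globin genes Hba-a1 (1129 bp) and Hba-a2 (1216 bp) had a region in the list labelled BN1 only, but they are near-identical copies, so reads could not be assigned to one of them with certainty.

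B lymphoid genes showed the same direction (median 141.8 bp per Mb, above all 10000 random lists), although the median was 69.0 at a −log10 q of at least 10, and 14.8 at percentile 91.5 with the top 10000 peaks of each list. Of 21 genes, 16 were longer in the list labelled BN1 and 4 in the list labelled control (Bank1, Il7r, Rag1 and Rag2), against 10 and 8 at a −log10 q of at least 10 and 10 and 5 with the top 10000. End regions were present in the list labelled BN1 only at 11 genes. Among these, the B cell receptor component Cd79b had 7975 bp, and the transcription factors Ebf1 and Pax5 had 5757 and 5751 bp, each against none in the list labelled control.

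The dendritic cell list (percentile 98.9) and the megakaryocyte and platelet list (percentile 1.04) lost their place outside the central 95% under several settings. The first holds genes that B cells also use. Among its members whose end regions differed, Spib (9064 against 695 bp), Bcl11a (5555 against 0 bp) and the class II genes H2-Eb1 (5222 against 242 bp) and H2-Aa (3897 against 0 bp) led, all longer in the list labelled BN1. Of its 17 genes, 11 were longer there and 4 in the list labelled control. Among those 4 were Tcf4 (11334 against 3359 bp) and Id2 (6531 against 435 bp), both with end regions in both lists. Clec9a, a dendritic cell lectin receptor (2677 against 0 bp), was another. The percentile of this first list was 36.6 at a −log10 q of at least 5, with a median of 0. The second had a median of only -1.30 bp per Mb, with 11 of 20 genes longer in the list labelled control and 3 in the list labelled BN1. Pf4 (platelet factor 4) had 2651 bp in the list labelled control and none in the other, whereas Gp9 (1366 bp) and Thbs1 (1319 bp) had a region in the list labelled BN1 only. Its percentile was 47.2 at a −log10 q of at least 5 and 11.7 with lengths in bp.

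The stem and multipotent progenitor list did not stand apart (percentile 47.7, median 0, mean 69.6 bp per Mb). Of its 22 genes, 8 were longer in the list labelled control, 6 in the list labelled BN1 and 8 had no region. Kit, the gene of the sorting marker, had no called region within 10 kb in either list, nor had Gata2. The gene of the stem cell marker Cd34 had 1601 bp in the list labelled control and none in the list labelled BN1, and Ly6a (Sca-1) had 6831 and 1948 bp, although its difference, BN1 minus control, was 192 bp with the top 10000 peaks of each list. Erg, an ETS factor of stem cells, had 15215 bp in the list labelled BN1 and none in the other. Leukaemia self-renewal genes outside the Hox clusters also stayed within the random range (percentile 34.3, median 0, mean 2.39). That range ran from 0 to 27.7 bp per Mb, so ties at 0 weigh here too. In bp, 11 genes were longer in the list labelled control and 7 in the list labelled BN1. The largest differences in bp within the self-renewal genes were at Bcl2 (13503 against 1203 bp) and Runx2 (13132 against 4760 bp), both longer in the list labelled control. Meis1, given above, also belongs to these genes. Sox4 (4907 bp) and Myb (3835 bp) had regions in the list labelled BN1 only. Myc had an end region in both, with 4443 bp in the list labelled control and 1808 bp in the list labelled BN1.

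Of the remaining lists, those with a random range lay within it. The cell cycle list stood at percentile 96.4, with a median difference of 28.4 bp per Mb but -61 bp unscaled. Counted in bp, 14 of its genes were longer in the list labelled control, led by Ccnd1 (cyclin D1, 11251 against 0 bp), and 11 in the list labelled BN1. Some of the 14 turned per Mb, such as Aurkb (-285 bp but 107.4 bp per Mb) and Pcna (-241 bp but 51.0). Fusion partners and their complexes stood at percentile 91.7 (median 52.6 bp per Mb, but -852.5 bp unscaled) and at 99.7 with the top 10000 peaks of each list. Brd9 had an end region in both lists, with 1296 bp labelled control and 1720 bp labelled BN1. Nutm1 had no end region in either, and the 4844 bp labelled control and 4705 bp labelled BN1 within its window, a difference that changed sign per Mb (89.9), need not belong to it. Interferon response genes stood at percentile 89.1 (98.3 with lists of equal length), housekeeping genes at 78.1 (median 35.2 bp per Mb, but -832.5 bp unscaled) and inflammatory and immediate early genes at 13.8 (median -5.85 but mean 9.30 bp per Mb). The Hoxc, Hoxd, T and NK lymphoid, mast cell and basophil, eosinophil, stroma and endothelium, and other tissue lists each had a median of 0, as did the central 95% of their random lists, so the percentile could not place these 7 lists. All of the 3 Hoxc genes with a region were longer in the list labelled control, and the Hoxc list stood at percentile 0.01 with 50 kb flanks. The mast cell list nonetheless held Mitf, a melanocyte and mast cell factor that macrophages and osteoclasts also use, with 20016 bp in the list labelled control and none in the list labelled BN1, and Hdc, which went the other way (0 against 11798 bp). Of 16 housekeeping genes, 15 had an end region in both lists, and of 18 genes of other tissues, 17 had one in neither.

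Gene by gene, 799 genes had at least 5 kb more acetylated length in the list labelled control and 107 in the list labelled BN1, a size chosen after the values were seen. Expressed as a share of each list's covered length, the same size of difference was found for 377 and 368 genes. The 10 genes with the largest excess in the list labelled control were Zmiz1, a transcriptional coregulator (51223 against 9769 bp), Nav1 (38788 against 640 bp), Vps13d (38139 against 5270 bp), Mgat5, an N-glycan branching enzyme (34940 against 4269 bp), Chchd6 (29745 against 239 bp), the endocytic receptor Lrp1 (29568 against 335 bp), Aopep (28799 against 1868 bp), the transcription factor Creb5 (29731 against 4132 bp), Niban2 (26271 against 1147 bp) and the mTORC1 subunit Rptor (29279 against 4263 bp). Strongest within Zmiz1 in that list was a peak on chromosome 14 from 25466110 to 25478134 with a fold enrichment of 24.9.

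In the list labelled BN1 the largest excess was at Sgms2, a sphingomyelin synthase (18240 against 2306 bp), Erg (15215 against 0 bp), Ripor2 (14686 against 0 bp), Gfod1 (14284 against 0 bp), Gsr, glutathione reductase (16104 against 2053 bp), Lhpp (16077 against 2238 bp), Hvcn1, a voltage-gated proton channel (13719 against 0 bp), Tbc1d2b (16044 against 3076 bp), Hdc, the histamine-forming enzyme (11798 against 0 bp), and Sema4b (12588 against 988 bp). Within Erg the strongest peak of that list lay on chromosome 16 from 95455648 to 95459156, inside the gene, with a fold enrichment of 14.8.

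Broad acetylated domains were more frequent in the list labelled control. Stitching peaks within 5 kb gave 171 domains with at least 10 kb covered in that list and 35 in the list labelled BN1, holding 7.77% and 2.35% of the covered length. Of these, 15 in each list overlapped a broad domain of the other. The 5 longest in the list labelled control by covered length lay at Zmiz1 (31750 bp), Plekho2 (31695 bp), Lrp1 (28801 bp), Niban2 (26948 bp) and Lcp1, the gene of the leukocyte actin-bundling protein L-plastin (25141 bp). All of them except the one at Plekho2 met no broad domain of the other list, as did one at Kxd1, Fkbp8 and Ell on chromosome 8 (23989 bp). In the list labelled BN1 the longest lay on chromosome 8 from 126815865 to 126853226 outside protein-coding genes (20327 bp), at Irgc1 and Plaur (17364 bp), on chromosome 9 from 123923111 to 123945321 outside protein-coding genes (17086 bp), at Myh9 (16906 bp) and at Fam53b (16549 bp). Those at Plaur, Myh9 and Fam53b met no broad domain of the other list, as did one on chromosome 15 from 74917918 to 74936879 outside protein-coding genes (16183 bp) and one at Gsr (16104 bp). Some of these differ by the 10 kb minimum only. The other list covered 9282 bp within the Myh9 domain, 9569 bp within that on chromosome 15 and 9639 bp within that at Lcp1. At Lrp1 it covered 335 bp and at Fam53b 1663 bp. With lists of equal length the domain counts were 127 and 35, a ratio of 3.63.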

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

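Regions on unplaced contigs, which entered no gene comparison, numbered 28 in the list labelled control and 8 in the list labelled BN1, or 0.0988% and 0.0418% of the peaks. They are given because they lie outside the comparisons and exceed the 3 that a count of 0 allows, which does not show that such peaks were unusual; no explanation was tested.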

How the results depend on the processing

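The setting with the top 10000 peaks of each list was chosen after the results were seen, and the others were fixed before. No paired analysis was possible because each group had 1 ChIP library, which also rules out leaving a replicate out. Motif comparisons were not run, since no genome sequence was used. Medians and lengths were taken as moved beyond 10% of their value, shares beyond their 95% interval and counts beyond 1.5 times. Unknown read depth limits what a missing region means in either list, and the cause of the changes below was not tested.

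At a −log10 q of at least 5 the median widths, control then BN1 as in all pairs below, were 1040 and 933 bp. At 10 they were 1361 and 1182 bp, with 14880 and 11054 peaks covering 24.3 and 15.3 Mb. Shared peaks were 47.2% and 66.8% at 5, 53.0% and 71.6% at 10, 54.0% and 57.0% with lists of equal length, 27.6% and 40.9% with at least 50% of both regions overlapping, 36.5% and 53.9% with summits within 500 bp, and 63.3% and 63.9% with the top 10000, where 36.0% of the union was covered by both. With at least 50% of both regions overlapping, the median fold enrichment of shared peaks was 12.1 and 12.9.

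At gene ends lay, for shared control, unshared control, shared BN1 and unshared BN1 peaks in turn, 70.5%, 15.5%, 68.3% and 18.4% at 5; 76.4%, 21.5%, 74.99% and 30.2% at 10; 69.1%, 14.7%, 65.3% and 17.5% with equal length; 62.5%, 10.01%, 60.0% and 11.3% with a 500 bp window; 70.1%, 21.2%, 68.4% and 22.3% with a 2500 bp window; and 79.2%, 25.9%, 77.7% and 43.7% with the top 10000. Shared peaks were more often at gene ends than unshared ones in each of these. Genes with an end region in 1 list only, 1450 and 706 in the full lists, numbered 1115 and 1074 with equal length and 1006 and 1651 with the top 10000, where the direction turned.

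Genes at least 5 kb longer numbered 480 and 59 without flanks, 2414 and 325 with 50 kb flanks, and 377 and 368 per covered length; with the top 10000 they numbered 410 and 89. Without flanks 1 gene list, monocyte and macrophage, lay below the central 95%. The megakaryocyte list was inside it at 5, at 10, with equal length, without flanks, in bp and with the top 10000. The dendritic list fell to percentile 36.6 at 5, 37.2 at 10 and 43.3 with the top 10000, with a median of 0 in each, and to 74.1 with 50 kb flanks. Lists that moved outside were Hoxc (0.01 with 50 kb flanks), interferon response (98.3 with equal length) and fusion partners (99.7 with the top 10000). The Hoxa, Hoxb, monocyte, neutrophil, erythroid and B lymphoid lists stayed outside on the same side under each setting, except Hoxa (50) and Hoxb (44.4) without flanks and B lymphoid with the top 10000 (91.5). Their sizes moved more: with the top 10000 the neutrophil median was 7.30 bp per Mb in place of 126.8, the monocyte median -6.35 in place of -34.6, the B lymphoid median 14.8 in place of 141.8, the erythroid median 25.3 in place of 37.9, the Hoxa median -185.6 in place of -114.7 and the Hoxb median -96.0 in place of -25.4. With equal length they were, in that order, 121.6, -35.0, 135.4, 41.0, -116.6 and -31.1; at 5 they were 92.8, -55.6, 131.2, 41.0, -127.6 and -27.9; at 10 they were 61.5, -18.6, 69.0, 47.2, -147.7 and -76.4; without flanks 32.1, -15.7, 35.9, 26.998, 0 and 0; and with 50 kb flanks 226.4, -125.2, 137.1, 59.6, -198.3 and -189.0.

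Differences of some named genes, BN1 minus control, changed sign. Cebpa turned to 402 bp at 5, 866 bp at 10 and with equal length, 867 bp without flanks and 17.6 bp per Mb. Nutm1 turned to 585 bp at 5 and with equal length, 284 bp with the top 10000 and 89.9 bp per Mb. Isg15 turned to 108 bp at 10 and with the top 10000, 353 bp with equal length and 18.7 bp per Mb. Skida1 turned to 16 bp at 10 and with the top 10000 and 28.0 bp per Mb. Lmo2 turned to -259 bp at 10 and with the top 10000, and Ly6a to 192 bp with the top 10000. With 50 kb flanks, Bub1 turned to -492, Ermap to -275, Gp9 to -6657, Ifit2 to -5282 and Il5ra to -1451 bp.

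Broad domains numbered 106 and 23 at 10, 89 and 16 with 2 kb stitching, 337 and 84 with 12 kb, and 72 and 20 with the top 10000. Domains of the BN1 list overlapping one of the control list numbered 9 at 5 and with equal length, 7 at 10, 5 with 2 kb stitching and with the top 10000, and 38 with 12 kb.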

Other observations

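The tests on list length by itself for the gene lists and on an exchange of the lists were chosen after the results were seen. So were those on a difference between the cells and on the genes without a region. Those on length together with calling depth and on broad domains are recorded as written before, but they address patterns taken from the full lists. The setting with the top 10000 peaks of each list, which the depth test uses, was itself added after the data were examined.

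Among the unshared peaks, which were ranked by fold enrichment after the lists had been examined, the strongest in the list labelled control was on chromosome 1 from 64301192 to 64302194 (fold enrichment 61.8), 178846 bp from Klf7. Others lay inside Clmp (45.2) and Anxa4 (44.0) and 83342 bp from Vav3, a guanine nucleotide exchange factor of blood cells (37.9). In the list labelled BN1 the strongest was on chromosome 1 from 181859240 to 181863626 (51.2), 16838 bp from Lbr, which encodes the lamin B receptor. Another lay 17592 bp from Cxcr4, the chemokine receptor of marrow retention (34.8), and others lay at Zeb1 (31.5) and at one end of Bach2, a transcription factor of B cells (28.1).

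Hoxa and monocyte genes were acetylated mainly in the list labelled control, and neutrophil, erythroid and B lymphoid genes mainly in the list labelled BN1. With equal numbers of peaks, 5 of 5 gene lists stayed outside the central 95% in the same direction. Peak number by itself therefore does not account for all of this. Their medians were -116.6 bp per Mb for Hoxa, -35.0 for monocyte, 121.6 for neutrophil, 41.0 for erythroid and 135.4 for B lymphoid genes. These 5 come from the 8 lists that lay outside it in the full data. Of the 8, Hoxb (percentile 0.08) and dendritic cell (99.4) also stayed, whereas megakaryocyte was at 43.9. Because the medians were already scaled by covered length, this setting tests list length only weakly. Length together with calling depth stays open, since with the top 10000 the list count was 4 of 5 (B lymphoid percentile 91.5) and the median went from 126.8 to 7.30 for neutrophil, from -34.6 to -6.35 for monocyte and from 141.8 to 14.8 for B lymphoid genes, while it was 25.3 in place of 37.9 for erythroid and -185.6 in place of -114.7 for Hoxa genes. An exchange of the lists between the labels stays open because the peak name prefixes read the other way from the titles; that genes of 3 of 3 mature lineages lay above the central 95% in the list labelled BN1 restates the pattern and decides nothing. A difference between BRD9-NUTM1 and control cells in the direction of the labels cannot be told apart from an exchange with 1 library per group.

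No region was called at Kit, Mpo, Elane, Prtn3 or Ms4a3 in either list, although the labels describe a sort for cKit. Housekeeping genes were not generally missed, since 93.8% of them (15 of 16) had an end region in both lists. This cannot show whether less widely acetylated genes were missed. Peak numbers ran to 28343 and 19148 with 0 missing, so the numbering had no gap. Peaks removed from its end or before naming would leave no gap either. Mature cells, which the cKit sort should have removed, stay open and were not tested independently. In the list labelled BN1, 8 of 9 late neutrophil and granule genes (Camp, Ltf, Ngp, Lcn2, Mmp8, Mmp9, S100a8, S100a9 and Cxcr2) had an end region. Of the 5 early ones (Mpo, Elane, Prtn3, Ctsg and Ms4a3), 1 had an end region. Ly6g, with no region in either list, was placed in neither set. Because 4 of the 5 early genes define the pattern, the gap of 68.9 percentage points restates it. In the list labelled control, 3 of the 9 late and 0 of the 5 early genes had an end region. Weak acetylation under the calling threshold at the genes without a region stays open.

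Broad domains were 4.89 times as many in the list labelled control. The number of peaks and weak bridging peaks may add to this but do not account for all of it. With equal numbers of peaks the ratio was 3.63, and with peaks of a −log10 q of at least 10 it was 4.61. Covered length was not made equal, being still 24.3 Mb (control) and 15.3 Mb (BN1) at that minimum, so its part stays open. Sequencing depth and enrichment, which the lists do not record, and a difference between the cells stay open.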
